A study of Mus musculus with 6 samples.

How the data were processed

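Gene expression was measured in lungs of C57 mice on 6 two-colour spotted arrays. Per the labels, each array carried amplified lung RNA of 1 mouse that had been sensitized and challenged with ovalbumin (OVA) and, in the other channel, a pool of amplified lung RNA of control C57 mice. The values are the log ratios that the authors deposited for each array, 1 per spot, and they were read here as log2 ratios. Their scanner, background correction, normalization and spot filter are not given in the sources used here. Neither is the base of the logarithm: a base of 10 would need ratios beyond the range of a common scanner, but a natural logarithm cannot be excluded, and it would make every fold larger than printed. The direction of the ratio and the dyes are not given either. Titles name the OVA mouse first, which made OVA over pool the likely direction before the data were examined, but the values of known response genes lie on the other side. Ratios are therefore printed with their deposited sign, sizes are given as folds apart, and neither sign is assigned to the OVA mice.

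The table has 17280 probes. The annotation of the platform gives 1 gene symbol for 14722 of them, several for 1 and none for 2557, and 14445 symbols were updated through a table of mouse genes (assembly GRCm38.p6, used for names alone), while 277 kept their older name. The deposited values had medians of -0.003, -0.012, 0.004, 0.003, 0.008 and 0.001 in mice 1 to 6 over the probes measured on all arrays, and each array was centred on that median. A set of 170 rows that repeat 10 sequences 17 times each and 4 plant control rows were left out of the tests. The repeated rows gave the technical spread, with a median SD within an array between 0.0812 and 0.226 for the 10 sequences. Probes measured on at least 4 of 6 arrays were tested, 11629 in all, of which 10373 had 1 symbol and stood for 9774 genes. In 563 genes with several tested probes, 5 had probes past the threshold on opposite sides.

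The log2 ratio of each probe was tested against 0 with limma 3.58.1 in R 4.3.3 (lmFit with an intercept alone, eBayes, two-sided), and p-values were adjusted with the Benjamini-Hochberg method at 0.05. A fold floor of 2 was set beside the test. The pool is 1 control sample shared by all arrays, so the test leaves out the spread between control mice, and without a known dye swap a dye effect of a single gene does not cancel. The number of arrays limits the precision. Gene lists were fixed before the data were examined, and 30 of the 31, those with at least 4 measured genes, were tested with limma's camera at a preset inter-gene correlation of 0.01, with 1 probe per gene and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were run beside it on the genes measured on all arrays, since they cannot take missing values. Fry tests whether the genes of a list move on balance to 1 side and does not compare them with other genes. Scores of lists were compared across mice by exact permutation of the 720 pairings. Genes were named by a rule fixed beforehand: the 12 highest and 12 lowest mean ratios among probes past the threshold, measured on all arrays with the same sign, up to 4 members per list past the threshold, or up to 2 given as values where none passed, and the 10 probes with the largest SD. F13a1, Stmn1, Masp1, Tslp, Il4, Il5, Il13, Bhlhe40, Cxcl15, Mroh4, Tex19.2, Lgi1 and Acss2 lie outside this rule and were chosen after their values were seen. The same holds for S100a8, Ltf, Prg2, Siglecf, Cpa3, Tpsb2 and Tpsab1. Library clones without a gene name were passed over.

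The fit was tested on simulated data in which 200 of 11629 probes were changed. It recovered 93.5% of changes of 1.5-fold, 98% of changes of 2-fold and all changes of 4-fold, with 8, 10 and 9 false calls. The changed probes were drawn at random whatever their spread, so these shares hold for a typical spread (median SD 0.16). They do not describe genes with a large spread. Car3, 3.37-fold apart with an SD of 1.65, did not pass in the real data (limma, adjusted p = 0.0558). Only these 200 probes were changed, so a deviation of the shared pool or a dye effect was not part of the simulation. The false calls therefore describe the simulated data and do not estimate how many calls in the real data are false. Alternatives were no centring, scaled or quantile-normalized arrays, other minimum numbers of arrays, array weights, robust eBayes, unmoderated variances, genes in place of probes, stricter thresholds, other list tests and leaving out each mouse. Omitting probes that lie beside a stronger probe, and keeping the repeated and plant rows, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.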

Results

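Lungs of 6 C57 mice sensitized and challenged with ovalbumin, a protocol that produces allergic inflammation of the airways, were each compared on a two-colour array with a single pool of lung RNA from control C57 mice. The comparison asks which transcripts differ between the OVA lungs and the control pool. The arrays measured 12294, 12140, 11599, 12322, 10922 and 13132 probes in mice 1 to 6, and the SD of the log2 ratio over probes was 0.47, 0.42, 0.21, 0.36, 0.32 and 0.37. The array of mouse 3 stood apart: 14 of its probes lay at -1 or below and 13 at 1 or above, against 349 and 194 in mouse 1. Its Pearson correlation with the other arrays, taken across 8663 probes that are not independent replicates, was between 0.17 and 0.42. Signs below are those of the deposited ratio, whose direction the labels do not settle, and folds assume a logarithm of base 2.

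Among genes with the same sign in all 6 mice, the lowest mean ratios included members of the chemokine, interferon and mucous cell lists. Saa3, an acute-phase serum amyloid, had a mean log2 ratio of -3.85 ± 2.15 (SD, n = 6), 14.4-fold apart from the pool (limma, Benjamini-Hochberg adjusted p = 0.0113). It was at -0.007 in mouse 3, without which it was 24.5-fold apart. Slc26a4, the anion exchanger pendrin, was at -2.93 ± 1.32 (adjusted p = 0.00648), and the interferon-induced Oas1g at -2.73 ± 1.44 (adjusted p = 0.01). Slfn4 at -2.45, the chemokines Ccl9 at -2.38, Cxcl9 at -2.24 and Ccl3 at -2.04, Ms4a6d at -2.22, the interferon-inducible Ifi204 at -2.16, the Fc receptor Fcgr1 at -1.87 and the inhibitory receptor Lilrb4a at -1.73 were also negative in 6 of 6 mice. In mouse 3, though, they lay between -0.547 for Ccl9 and -0.072 for Slfn4, and Oas1g was at -0.005. Where that value is near 0, its sign carries little weight. Sar1a, a GTPase of transport from the endoplasmic reticulum, was at -2.82, but its probe lies 18 numbers from that of Clca1, and probes at this distance had correlated ratios. The highest means included members of the adipocyte, heart muscle and club cell lists. The immunoglobulin heavy chain probe Igh was at 2.48 ± 0.64 (5.58-fold, adjusted p = 0.00233), the adipocyte hormone Adipoq at 2.30 ± 1.30 and the lipid droplet protein Cidea at 2.25 ± 0.69. Gsta3, Gstm3 and Ephx1, enzymes that conjugate or hydrolyse foreign compounds, were at 2.13, 1.45 and 1.57. Cox8b, Myl4, Nppb and Myh6, which are abundant in heart muscle, were at 1.77, 1.60, 1.45 and 1.44, and the airway secretory proteins Bpifa1 and Scgb1a1 at 1.62 and 1.38.

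**Figure D1:**
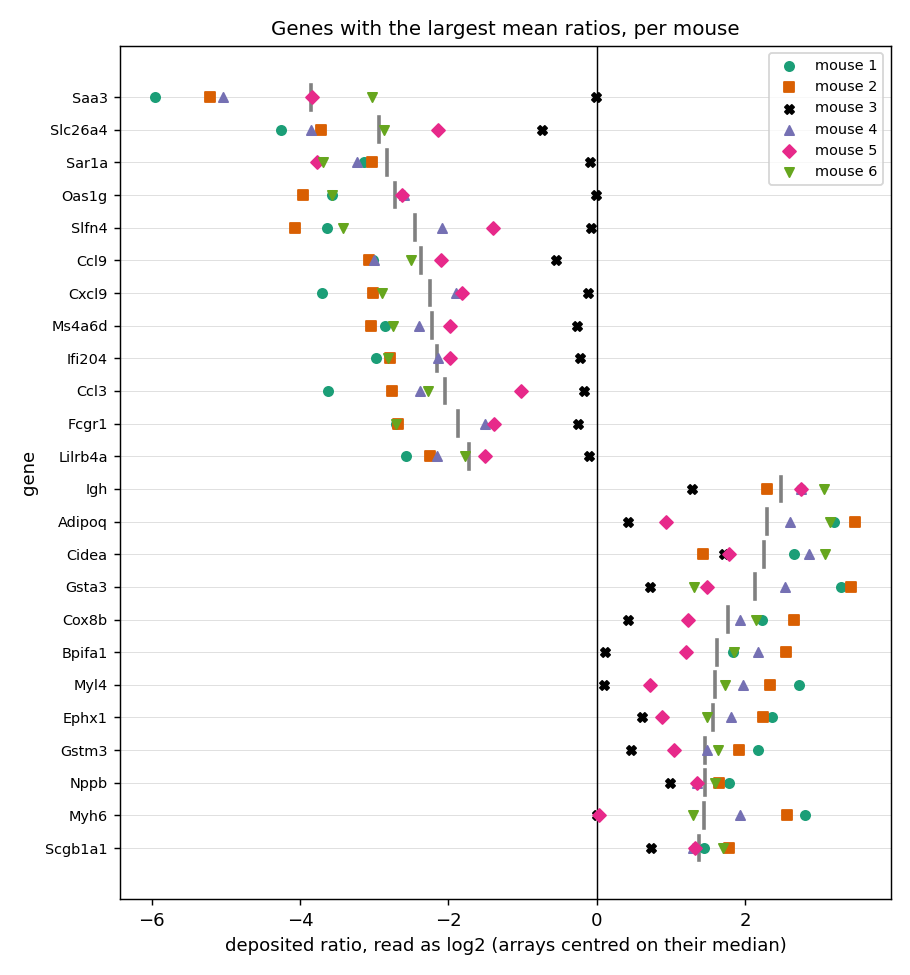
Deposited ratio, read as log2 and centred per array, of the 12 lowest and 12 highest genes that had 1 sign in all mice. Symbols are single mice and grey bars their mean; mouse 3 lies nearer 0 than most others, as for Saa3 at -0.007 in mouse 3 and -5.95 in mouse 1.

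In all, 2832 of 11629 probes passed an adjusted p of 0.05 in limma, 1431 with a negative and 1401 with a positive mean, and 4564 had an unadjusted p under 0.05. Among the 2832, 174 were at least 2-fold apart, 124 negative and 50 positive. Of the 8663 probes measured in all mice, 30.2% had the same sign in every mouse. Independent signs would give 3.12%, but all ratios share 1 pool, which alone raises this share by an amount not estimated here. The count depended on single mice: leaving out mouse 4 or mouse 2 left 1325 or 1376 probes, 113 or 109 of them at least 2-fold apart, and leaving out mouse 6 left 1708. Without mouse 3 there were 3036, of which 2509 were shared with the full set, and 248 were at least 2-fold apart.

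Of the 30 gene lists tested, 18 passed camera at the preset correlation, 11 on the negative and 7 on the positive side. With a correlation estimated per list 0 passed in camera and 0 had an unadjusted p under 0.05 (lowest 0.0521), and for 16 of the 18 the value was adjusted p = 0.41 with an estimated correlation, as it is for each of these lists below where no other is given. Fry, run on the genes measured in all mice, called 19 lists. Probes 6, 18 or 24 numbers apart had correlated ratios, and those of F13a1, Stmn1, H2-Eb1, Vcan, Tek, Myh6, Fasn, Atf3, Klf4 and Arntl, beside Sar1a and Mylpf, lie so far from a stronger probe of the same sign. Without all such probes, a choice made after seeing the data, 2650 probes passed and 157 were at least 2-fold apart.

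The mucous cell list was negative in its median (-0.34, camera adjusted p = 5.74e-05), and 10 of its 20 measured genes passed the test, all negative, with 15 when adjusted over the list alone. Clca1, a secreted regulator of mucus, was at -3.06 ± 1.95 (SD, n = 6), the airway gel-forming mucin Muc5ac at -2.63 ± 1.70 and Agr2, which assists mucin folding, at -1.33 ± 1.04. The list of alternatively activated macrophages (median -0.62, adjusted p = 0.000632) had 11 genes on the negative and 1 on the positive side among 19, and 14 passed adjusted over the list alone. The positive gene was the clotting factor subunit F13a1 at 0.70. Its largest ratios were those of Retnla, a resistin-like secreted protein, at -2.81, the arginine-degrading enzyme Arg1 at -2.26, the eosinophil-associated ribonuclease Rnase2a at -1.91 and the glucan receptor Clec7a at -1.76. Clca1, Muc5ac, Retnla and Arg1 were negative in 5 of 6 mice, the exception being mouse 3 with 0.84, 0.22, 1.00 and 0.14. Without mouse 3 their means were -3.84, -3.20, -3.58 and -2.75.

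Chemokines (median -0.57, adjusted p = 8.88e-06) had 10 negative and 1 positive call among 23 genes, and 20 adjusted over the list alone. Beside the chemokines already named, Ccl8, a monocyte chemoattractant, was at -2.28 in the 5 mice with a value. Interferon-responsive genes (median -0.68, adjusted p = 3.79e-06) had 16 negative calls and 1 positive call among 27, and 20 adjusted over the list alone, with Oasl1 at -1.98, Ifit2 at -1.84 and the GTPase Gbp3 at -1.57. Complement (median -0.27, adjusted p = 0.00694) had 8 calls among 13 genes, all negative, and 9 adjusted over the list alone, the added one being positive (Masp1 at 0.135). It was led by factor B (Cfb) at -1.71 and the C1q chains C1qa at -1.36 and C1qb at -1.34. Macrophage and lysosome genes (median -0.21, adjusted p = 0.00489, and adjusted p = 0.47 with an estimated correlation) had 9 negative calls and 1 positive call among 26, with 13 adjusted over the list alone. Aif1, a macrophage marker, was at -1.80 and the proteases Ctsc and Lgmn at -1.68 and -1.16. Antigen presentation on class II molecules (median -0.48, adjusted p = 0.00298, and adjusted p = 0.47 with an estimated correlation) had 6 calls among 13 genes, all negative, and 8 adjusted over the list alone, with H2-Aa at -0.82, H2-Eb1 at -0.64 and Ifi30 at -0.63. Neutrophil genes (median -0.19, adjusted p = 0.00219) had 4 calls among 15, all negative, and 8 adjusted over the list alone. These were Chil1 at -1.31, Cd177 at -1.15, Mmp8 at -0.41 and Mpo at -0.15. Chil1 is also in the alveolar type 2 list. The neutrophil genes S100a8 and Ltf had no call, at -0.07 and -0.06, with single mice on both sides of 0.

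Cell cycle genes were negative in their median (-0.54, adjusted p = 5.96e-07): 20 of 33 passed, all negative, and 26 adjusted over the list alone, 25 negative and 1 positive, Stmn1 at 0.46. The mitotic kinase Cdk1 was at -1.99, the ubiquitin-conjugating Ube2c at -1.39, cyclin Ccnb2 at -1.37 and the spindle kinase Aurka at -1.23. Matrix genes (median -0.37, adjusted p = 0.000464) had 14 negative and 2 positive calls among 28, and 20 adjusted over the list alone, with the fibrillar collagens Col3a1 at -1.67, Col1a1 at -1.45 and Col5a2 at -0.91, and the proteoglycan Vcan at -1.08. Protein folding in the endoplasmic reticulum (median -0.22, adjusted p = 4.81e-05) had 10 calls among 24, all negative, and 10 adjusted over the list alone. The chaperones Calr, Hsp90b1 and Hspa5 were at -1.36 ± 0.32, -1.19 ± 0.27 and -0.87 ± 0.30, and the disulfide isomerase Pdia3 at -0.88 (n = 6 each).

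On the positive side, the list of club cells, the secretory cells of the small airways (median 0.95, adjusted p = 1.18e-06), had 13 positive calls and 1 negative call among 18 genes, and 16 adjusted over the list alone. The negative gene was the antimicrobial lectin Reg3g at -1.45. Ciliated cell genes (median 0.19, adjusted p = 0.0236) had 3 positive calls and 1 negative call among 11, and 8 adjusted over the list alone, with Tppp3 at 0.68, Dynlrb2 at 0.43, Nme5 at 0.38 and the dynein Dnah5 at -0.20. The ciliated list lost its call with probes measured on all arrays (camera adjusted p = 0.0737). Endothelial genes (median 0.22, adjusted p = 0.000973) had 9 calls among 24, all positive, and 10 adjusted over the list alone, including Ramp2 at 1.09, the angiopoietin receptor Tek at 0.93, the converting enzyme Ace at 0.87 and Acvrl1 at 0.71. Genes of oxidative phosphorylation (median 0.14, adjusted p = 0.000183) had 11 calls among 30, all positive, and 13 adjusted over the list alone. They included the cytochrome oxidase subunits Cox4i1 at 0.78, Cox6c at 0.41 and Cox6a1 at 0.33.

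Adipocyte and heart muscle lists were on the same side as the club cell list. The adipocyte list (median 0.44, adjusted p = 6.64e-07) had 9 calls among 15 genes, all positive, and 11 adjusted over the list alone. Ucp1, the uncoupling protein of brown fat, was at 1.32 ± 0.27 and Scd1, a fatty acid desaturase, at 0.98 ± 0.55 (n = 6). The heart muscle list (median 0.57, adjusted p = 3.79e-06) had 14 calls among 24, all positive, and 16 adjusted over the list alone. Skeletal muscle genes (median 0.14, adjusted p = 0.033) had 5 positive and 2 negative calls among 12, and 8 adjusted over the list alone. Tnnt3 was at 0.71 and Eno3 at 0.64, while Atp2a1 was at -1.30 and Mylpf at -1.10. The probe of Mylpf lies 24 numbers from that of Saa3. This list no longer passed without mouse 3 (adjusted p = 0.063). The heart muscle score was 1.17 in mouse 1 and 0.12 in mouse 3.

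**Figure D2:**
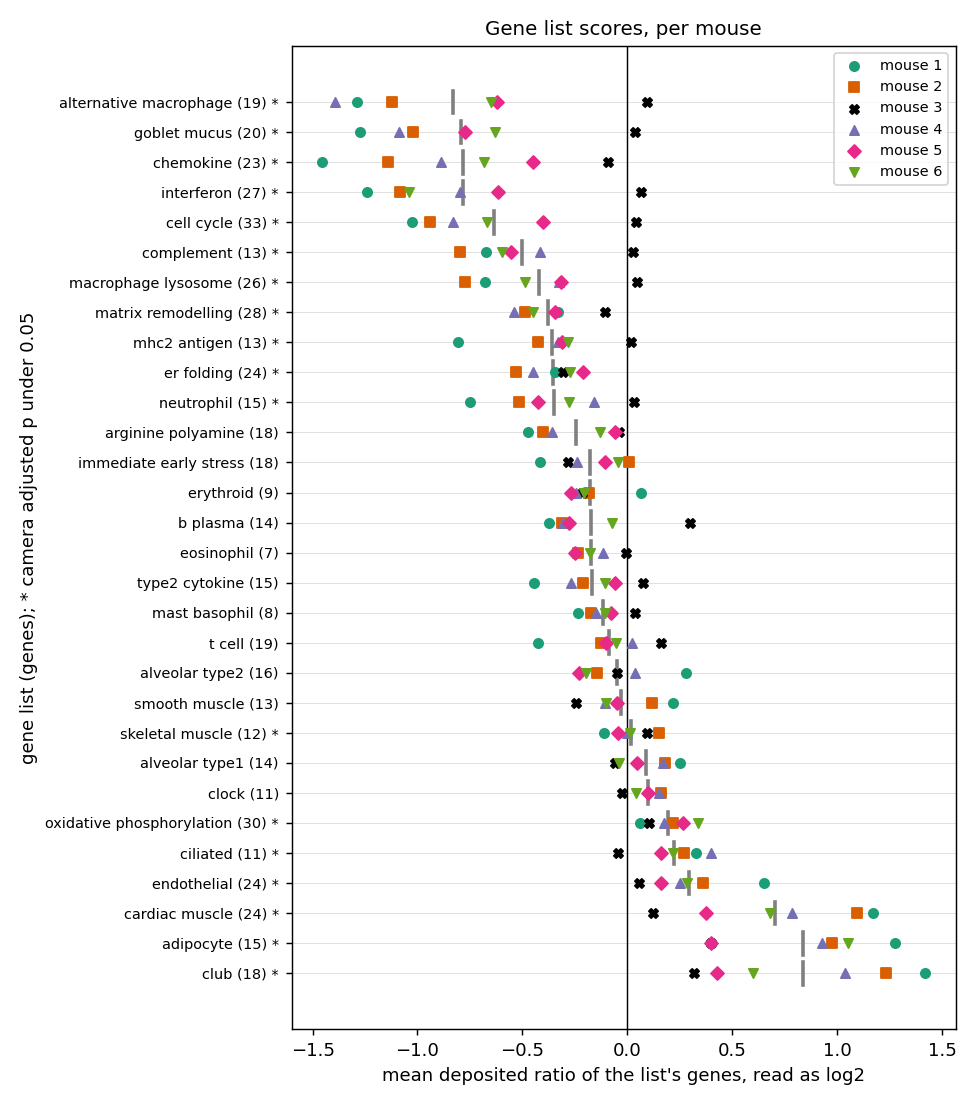
Mean ratio, read as log2, of the measured genes of each list in each mouse. Grey bars are means over mice, asterisks mark camera calls; in mouse 3 the interferon score was 0.07, while its score for folding in the endoplasmic reticulum, -0.31, lay among those of the others.

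The remaining lists did not pass camera. Eosinophil genes had a median of -0.05 over 7 genes (adjusted p = 0.268), with 1 call, Csf2rb2 at -0.89 ± 0.45, a receptor subunit, and 1 adjusted over the list alone. Of the 20 genes of this list 13 were on the array and 7 could be tested. Epx, Prg3, Il5ra and Ccr3 were not among the 7, so the median does not cover them. Prg2 and Siglecf were among the 7 and had no call, at -0.06 and 0.01. The eosinophil-associated Rnase2a, given above, was in the macrophage list. Type 2 cytokine genes had a median of -0.11 (adjusted p = 0.257), with 3 negative and 2 positive calls among 15 and 5 adjusted over the list alone. Il6 was at -1.25, Ccl1 at -0.78 and Il33, also an alarmin, at -0.61, against Gata3, the transcription factor of type 2 helper cells, at 0.51 and the alarmin Tslp at 0.46. The type 2 cytokines Il4, Il5 and Il13 themselves had no call, with values of -0.36, -0.21 and -0.18. T cell genes had a median of -0.01 (adjusted p = 0.565) and 3 calls among 19, also 3 adjusted over the list alone: the inhibitory receptor Ctla4 at -0.71, Foxp3 of regulatory T cells at -0.32 and the receptor chain Cd247 at 0.43. B and plasma cell genes had no call among 14 or adjusted over the list alone (median -0.21, adjusted p = 0.11), with Ms4a1 at -0.36 and Cd79a at -0.32 as values, and passed without mouse 3 (adjusted p = 0.00689). The immunoglobulin heavy chain probe Igh, at 2.48 as given above, was not in this list, so the median does not cover it. Mast cell and basophil genes had no call among 8 or adjusted over the list alone (median -0.03, adjusted p = 0.94), with Fcer1g at -0.70 and Mcpt8 at -0.43 as values. Of the 8 genes 4 were negative, and Cpa3, Tpsb2 and Tpsab1 were on the positive side at 0.17, 0.09 and 0.09. Without mouse 3, Fcer1g was at -0.96 and passed (limma, adjusted p = 0.00537). Arginine and polyamine genes had 2 negative calls and 1 positive call among 18 and 1 adjusted over the list alone (median -0.07, adjusted p = 0.268): Arg1, the arginine transporter Slc7a2 at -0.95 and the endothelial nitric oxide synthase Nos3 at 0.21. Alveolar type 2 genes had 5 negative and 3 positive calls among 16 and 9 adjusted over the list alone (median -0.09, adjusted p = 0.459), with the lipid synthase Fasn at 1.34 and the surfactant protein Sftpa1 at -0.61. Alveolar type 1 genes had 1 call on each side among 14 and 2 adjusted over the list alone (median 0.10, adjusted p = 0.268), Pdpn at -0.38 and Igfbp2 at 0.35. Smooth muscle genes had likewise 1 on each side among 13 and 2 adjusted over the list alone (median -0.015, adjusted p = 0.99), the calponin Cnn1 at -0.20 and Synpo2 at 0.17. Erythroid genes had 1 negative call among 9, the anion exchanger Slc4a1 at -0.57, and 1 adjusted over the list alone (median -0.16, adjusted p = 0.104). Immediate early and stress genes had 3 negative calls and 1 positive call among 18 and 4 adjusted over the list alone (median -0.09, adjusted p = 0.268), the factors Atf3, Myc and Klf4 at -0.96, -0.63 and -0.52 and Ier3 at 0.37.

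The genes with the largest SD between mice were Saa3 with 2.15, Retnla 2.11, Arg1 1.96, Clca1 1.95 and Muc5ac 1.70, while the median over all probes measured in 6 mice was 0.16. Mouse 3 carried much of this: without it the SDs of these genes were 1.16, 1.10, 1.75, 0.42 and 1.08. Of the lists, club cell genes had the largest median SD, 0.68 and 0.46 without mouse 3. The median SD of the mucous list was 0.52, and it was 1 of 24 lists above percentile 95 of 10000 random lists of their size, while that of the eosinophil list was at percentile 53.6. The carbonic anhydrase Car3, abundant in fat and muscle, had an SD of 1.65 around a mean of 1.75 that did not pass the test (adjusted p = 0.0558). Without mouse 3 its mean was 2.17 and passed (limma, adjusted p = 0.0224). Of 3 relations between list scores tested across the 6 mice, alternatively activated macrophage and mucous cell scores had a Pearson r of 0.969 (exact permutation p = 0.00833, adjusted p = 0.025) and a Spearman rho of 0.886 (exact permutation p = 0.0333, adjusted p = 0.0875). Without the 2 mice farthest from the median, mice 3 and 4, r was 0.956, and without mouse 3 alone it was 0.909. Eosinophil and mucous cell scores had r = 0.764 (exact permutation p = 0.0764, adjusted p = 0.115) and rho = 0.6 (exact permutation p = 0.242, adjusted p = 0.242). Leaving out mice 3 and 4 gave 0.689 and leaving out mouse 3 alone gave 0.105. Scores taken as medians in place of means gave 0.297 over the 6 mice. B and T cell scores had r = 0.73 (exact permutation p = 0.128, adjusted p = 0.128) and rho = 0.829 (exact permutation p = 0.0583, adjusted p = 0.0875), with r = 0.833 without mice 3 and 6 and 0.505 without mouse 3 alone. The labels give no batches, but the arrays of mice 1, 2 and 4 correlated with each other at 0.82 to 0.86 and those of mice 5 and 6 at 0.85, against 0.49 to 0.75 between these sets. Macrophage and mucous scores lay between -1.39 and -1.02 in mice 1, 2 and 4, between -0.77 and -0.62 in mice 5 and 6, and at 0.09 and 0.04 in mouse 3. The relation between them follows this split, and the sets hold too few mice to test it within them. Cell cycle and chemokine scores were also lowest, and club cell scores highest, in mice 1, 2 and 4. The split is therefore not particular to macrophage and mucous genes. Interferon scores did not follow it, with -1.04 in mouse 6 and -0.80 in mouse 4.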

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

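Of the tests in this part, those on mouse 3, on the dye and on neighbouring probes were chosen after the pattern had been seen, while the tests of the direction of the ratio and of the sign patterns of the arrays were set before the data were examined. A gap from 1 mouse to all others that is large against the whole range was found in 10 of 112 named genes and 1 of 30 list scores. Chance gives about 1 in 20 for independent values that were not selected. The named genes were chosen by their means and SDs in these data and are correlated, so that rate is no benchmark for them. The 1 of 30 list scores does not exceed it. In all 10 genes the mouse was mouse 3. It was on the positive side or near 0 for genes that were negative in the others: Clca1 at 0.84, Reg3g at 0.58, Clec7a at 0.27, Gbp3 at 0.11, Atf3 at 0.026, Oas1g at -0.005, Csf2rb2 at -0.024, Sar1a at -0.088 and Ifi204 at -0.23. For Igfbp2, positive in the others, it was at 0.043. The erythroid score of mouse 1, 0.063, lay above those of all other mice.

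The array of mouse 3 lay near 0 for most of the response. Over the 174 negative probes at least 2-fold apart in the other 5 mice and measured in mouse 3, it kept a median of 3.12% of their mean, and over the 70 positive ones 25% (95% bootstrap intervals 0.316 to 6.23 and 17 to 30.04). A single factor that shrinks the whole array is argued against by these intervals and by the list of folding in the endoplasmic reticulum, chosen after its values were seen, which kept 84.8% (58.9 to 130) where the interferon list kept -7.05% (-17.2 to 1.70). Loss of measured spots is argued against too, since mouse 3 had 11599 measured probes and mouse 5 had 10922. An animal that was not exposed or an exposed animal with a weak response cannot be told apart, as both predict that most negative probes, here 156 of 174, lie under 50% of the other mice.

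The sign of the ratio is the second pattern. If the ratio were OVA over pool, alternatively activated macrophage and eosinophil genes should be positive in mean. Instead the median of the first list was -0.62 (95% bootstrap interval over genes -1.26 to -0.23, 84.2% of 19 genes negative). That of the second was -0.05 (-0.16 to 0.01, 71.4% of 7 negative). The first list argues against this reading and the eosinophil interval spans 0. These intervals resampled genes and hold no spread between mice or of the pool. A candidate explanation is that the deposited ratio is pool over OVA, which would place mucus, macrophage, chemokine and cell cycle genes higher in OVA lungs, but this remains a hypothesis that no label settles. A dye effect common to all arrays might also give large ratios: the shares of 3.12% and 25% kept by mouse 3 argue against it for both sets, but rest on 1 array, so it stays open. Of 32 sign patterns of the 6 arrays, 1, the real one with 2832 probes, gave as many, and the highest of the others gave 3. The arrays share the pool and are not independent, so flipping whole arrays breaks up any shared deviation, whatever its cause. With 32 patterns the lowest possible share is 1 in 32. The test therefore does not exclude chance, and a chance deviation of the pool stays open.

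Probes 6, 18 or 24 numbers apart had correlated mean ratios, with r of 0.133, 0.102 and 0.106 across probes against at most 0.0375 at other distances from 2 to 300. Sharing of signal between spots at fixed distances, on the array or in the plates used for printing, could give this. The first test, on the neighbours of 178 probes at least 2-fold apart, did not meet its own criterion: their ratio turned to the sign of the strong probe was 0.118 in the mean of these distances, and the highest of 592 other distances gave 0.121. The criterion asked for each of these distances to lie above all others. Taken singly, in both directions, they gave 0.0758 to 0.195, so some lay above 0.121 and others below it. A second test, added because the first had failed, used what is left of each array after regression on the other 5 and gave a mean correlation of 0.12 (0.143, 0.105 and 0.111), with at least 0.0794 on every array, against at most 0.0416 at other distances. Genes of 1 family placed at these distances are argued against as the whole cause: among 102 named pairs of the same sign with the neighbour at 0.5 or beyond, 0% shared the letters of their symbols, and without that limit 1 of 444 did, Ccl17 beside Ccl8. The sharing of signal stays open, since the first test failed its criterion and the second met its own. The layout of the array is not given in the sources used here, and other orders of related genes were not tested.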

How the results depend on the processing

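No paired analysis was possible because there is 1 group, and each mouse has its own array. Leaving out 1 mouse at a time, the 2832 probes past the threshold ranged from 1325 without mouse 4 to 3036 without mouse 3 (1376 without mouse 2 and 1708 without mouse 6), the 174 probes at least 2-fold apart from 109 without mouse 2 to 248 without mouse 3, and the median SD between mice from 0.143 without mouse 1 to 0.162 without mouse 4. With the variance of each probe alone 1444 probes passed and 78 of them were at least 2-fold apart; an adjusted p under 0.01 left 746 of the 2832, and limma's treat test against a fold of 1.2, in place of the 2-fold floor, gave 108 against 174. Fewer arrays, a stricter threshold or a fold floor within the test account for part of these counts by construction, and other causes were not tested. Of the 18 gene lists, 0 passed camera with an estimated correlation, while every other setting run gave 16 to 19. Skeletal muscle was lost with probes measured on all arrays and without mouse 3 (adjusted p = 0.0586 and 0.063) and ciliated cells in the first of these (0.0737), and erythroid genes passed without mouse 1 (0.0495). With list medians in place of means, the macrophage and mucous scores had r = 0.887 and no longer passed (exact permutation, adjusted p = 0.0667); the cause was not tested. Centring, scaling, quantile normalization, array weights, robust eBayes and gene averages left the counts of probes within 1.5 times, with 2501 to 3431 probes and 159 to 193 at least 2-fold apart. Of the 112 genes named by the rule none reversed under the settings that kept them (101 in 2 settings), and 42 lost their call without mouse 2 and 42 without mouse 4. Signal over background is not given in the sources used here.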

Other observations

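The clock list, fixed before the data were examined, did not pass camera (median 0.14, adjusted p = 0.268), yet 6 of its 11 genes passed limma, also 6 adjusted over the list alone, and went to both sides, with fry's test for change to either side at an adjusted p of 0.000763. That test passed for 28 of the 30 lists, so it does not set the clock list apart. Dbp and Tef, output factors of the clock, were at 0.52 and 0.64 and the repressor Cry2 at 0.64. Arntl, the activator also called Bmal1, was at -0.59 and Bhlhe40 at -0.49; the probe of Arntl lies 18 numbers from that of the stronger Aurka. Times of tissue collection are not given in the sources used here.

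Some genes had nearly the same ratio in mouse 3 as in the other 5 mice, and they were picked after their values were seen. On the negative side these included the chemokine Cxcl15 (-1.29 in mouse 3 and -1.38 in the mean of the others) and Calr (-1.35 and -1.36). Mroh4 (-1.20 and -1.22), Tex19.2 (-1.151 and -1.055) and Lgi1 (-1.22 and -1.37) were also among them. On the positive side they included the lipid synthesis enzymes Fasn (1.25 and 1.36) and Acss2 (1.28 and 1.13). A dye effect common to all arrays or a deviation of the shared pool, both left open above, would give such ratios too. The probe of Fasn lies 6 numbers from that of Myh6. Among the 244 probes at least 2-fold apart in the other 5 mice, 18 negative and 11 positive ones kept at least 50% of the ratio in mouse 3.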
